A study of Homo sapiens with 3 samples.

How the data were processed

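RNA from 1 APAP-ALF liver explant and 2 healthy liver explants was extracted with TRIzol and made into stranded total RNA libraries, per the labels' protocols. The authors deposited a table of raw counts per Ensembl gene and a table of normalized values per gene symbol. Per the submitters' processing notes, HISAT2, Subread and edgeR were used with GRCh38. Tool versions, annotation, strand setting and the handling of reads that match several genes are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical paralogs can therefore be mixed. Columns were matched to livers by name, the control columns by the number they share with the healthy livers in the labels.

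The raw counts covered 43320 genes. Symbols came from a gene name table (105 identifiers had none), and coordinates and gene types from GENCODE release 29 (41790 identifiers matched). XIST, TSIX and Y-linked genes (187) were removed from all steps because the samples are from people, leaving 43133. The deposited normalized values are a signal on an unnamed scale that the authors made. For genes in both tables each value equals the raw count divided by a constant per library, 35.8 reads per unit in the APAP-ALF liver, 28.3 in Healthy 1 and 28.4 in Healthy 2. The ratio was constant within 0.1% for 99.9% of values, and 100% of values came out as whole reads within 0.02. These recovered reads are those of the raw table, so the count test on the genes of that table used the raw counts.

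The main test was edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, on 26236 genes after filtering. TMM factors were 1.12 for the APAP-ALF liver, 0.978 for Healthy 1 and 0.913 for Healthy 2. The spread comes from the 2 healthy livers alone, with 1 residual degree of freedom and 3.28 prior degrees of freedom shared across genes, so the APAP-ALF liver is assumed to vary like them. Standard errors are the log2 fold change divided by the square root of the F statistic. Values per liver are TMM-scaled CPM, and counts of genes outside both healthy livers used log2 CPM with a prior count of 2. Intervals and floors cover counting error only, at 95%. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scaling factors and filters, the legacy edgeR method, a minimum fold of 2, and leaving out each healthy liver.

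The fit was tested on simulated data with the mean levels of the healthy livers and the library sizes of all 3 libraries. There were 5 simulations with 200 changed genes each. With dispersion following the fitted trend, edgeR recovered 54.8% of 4-fold and 99.8% of 32-fold changes, and 2.89% of its calls were false, while DESeq2 recovered 72.8% and 100% with 7.30% of its calls false. With gene-to-gene scatter drawn at 3.28 degrees of freedom, edgeR recovered 0% and 0%, and DESeq2 recovered 40.6% and 98.2% while 63.6% of its calls were false.

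Before the data were examined, 30 gene lists (607 memberships, 580 measured, some genes in several lists), the tests, the alternatives and the rule for named genes were fixed. The place of each list's median was found among 10000 random lists matched on mean expression in 20 bins. Another 12 lists were written after the data had been seen and serve the closing observations only. The rule named, first, the 5 protein-coding genes with the largest and the 5 with the smallest log2 fold change at 10 CPM or more in the higher group and outside both healthy values. It took only genes past the adjusted threshold, and where fewer than 10 passed it filled the places by size. Second, it took 2 members per list, the largest among those passing or otherwise those of highest mean CPM. In its last part it always took ALB, CYP2E1, CYP3A4, HNF4A, MYC, CDKN1A, MKI67, HMOX1, AFP and SPP1. As no gene passed, all places of the first and second parts were filled. After the data were seen, HLA genes and a few genes whose expression can reveal an inherited deletion or variant of one person were passed over and the next in rank taken. This gave 68 genes, of which 1 is not reported here. For genes at 0 in a whole group the fold is a bound against a floor of 3 counts over the group, and no list median changed with such genes at their bound.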

Results

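Total RNA from 3 human liver explants was sequenced with a stranded total RNA library kit. One explant came from a patient whose liver carried the label APAP-ALF, read here as acute liver failure after acetaminophen (APAP), and 2 explants were healthy livers (Healthy 1 and Healthy 2). The comparison the design implies is the APAP-ALF liver against the healthy livers. The count table held 46586617 counts for the APAP-ALF liver, 41069827 for Healthy 1 and 43676143 for Healthy 2. Mitochondrial ribosomal RNA took 31.1% of the counts in the APAP-ALF liver, 21.4% in Healthy 1 and 23.3% in Healthy 2, and nuclear protein-coding genes took 58.9%, 66.1% and 66.8%. The 95% Wilson intervals of these shares were at most 0.029 percentage points wide and cover counting error only. With 1 APAP-ALF liver, every value of that group is a single measurement, and nothing separates the condition from that patient.

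The APAP-ALF liver carried more transcript of cell division genes and of most cytokine, matrix and bile duct marker genes than either healthy liver, by at least 2-fold. Most acute phase and metallothionein genes and some genes of the urea cycle, of gluconeogenesis and of drug-metabolising cytochromes P450 were lower by at least 2-fold. For the acute phase genes this depended on the scaling, with 13 of 22 lower by that much, and 9 with library-size scaling. MKI67, a marker of dividing cells, stood at 196 CPM (counts scaled to a common library size) against 0.349 in Healthy 1 and 6.07 in Healthy 2. SAA1, an acute phase protein made by hepatocytes, stood at 57.5 CPM against 8858 and 6372. Transcripts of HNF4A, a master regulator of hepatocyte identity, and of CYP2E1, the main enzyme that activates acetaminophen, were close to the healthy levels, at 212 CPM against 228 and 251, and at 2400 CPM against 2414 and 3089, and the sign of both differences turned with library-size scaling.

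In numbers, 729 genes lay at least 4-fold above both healthy livers and 301 at least 4-fold below both, among 26236 genes. Setting each healthy liver against the other 2 libraries in the same way gave 75 genes above and 234 below for Healthy 1, and 194 above and 213 below for Healthy 2. These counts involve no test. Against a single healthy liver the counts were 1341 and 1360 higher and 618 and 847 lower, and among genes at 1 CPM or more in every library they were 116 and 78. The edgeR quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p under 0.05 (smallest adjusted p 0.0935), with 3806 genes at an unadjusted p under 0.05, of which 2251 were higher and 1555 lower in the APAP-ALF liver. The higher share of these was 59.1%. It was 76.9% with library-size scaling, which moved all genes by 0.24 on the log2 scale, and 50.9% with upper-quartile factors. limma-voom also called 0 and 0. With library-size scaling edgeR called 238 higher and 28 lower, among genes at 1 CPM or more in every library 48 and 13, and with upper-quartile factors 3 and 0. DESeq2 called 628 higher and 478 lower, and it called 96 and 67 genes when Healthy 1 or Healthy 2 took the place of the APAP-ALF liver. In those swapped runs the spread came from the APAP-ALF liver and the other healthy liver. The APAP-ALF liver differed from Healthy 1 and Healthy 2 by a median absolute log2 difference of 0.513 and 0.538, against 0.413 between the healthy livers. A wider spread lowers the number of calls, so the swapped runs are no null for the main count. In simulated data with gene-to-gene scatter drawn at 3.28 degrees of freedom, edgeR recovered 0% of 32-fold changes and 63.6% of DESeq2's calls were false. With dispersion following the fitted trend alone, edgeR recovered 99.8% and 7.30% of DESeq2's calls were false. The 3.28 degrees of freedom were those estimated from the real libraries, whereas the trend alone holds no such scatter. What either count measures thus depends on that scatter. Recovery and false share also depend on the number of changed genes, set at 200 in the simulations and unknown here. Neither percentage can therefore be read as that of the real calls.

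**Figure D1:**
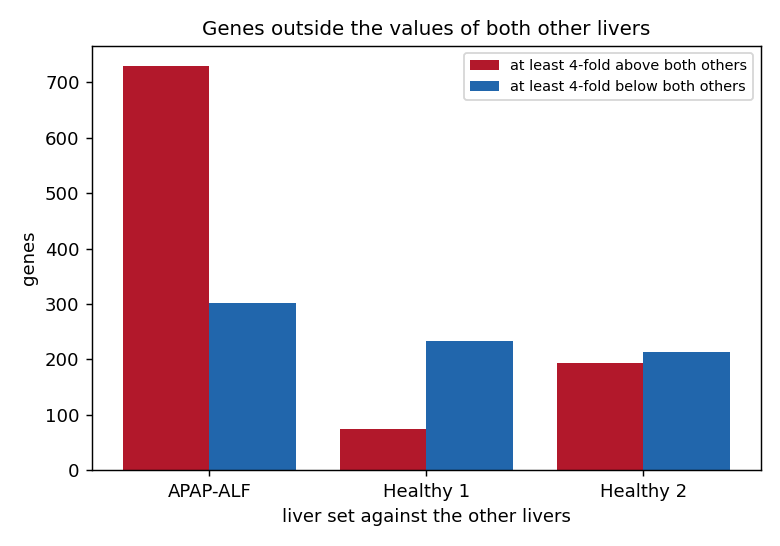
Number of genes (vertical axis) whose value in the named liver lay at least 4-fold above (red) or below (blue) the values of both other livers. The APAP-ALF liver has 729 genes above and 301 below, against 75 and 234 for Healthy 1 and 194 and 213 for Healthy 2.

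None of the genes named here passed the edgeR test after adjustment over all genes (adjusted p from 0.0935 to 0.984), so each is given by its values, as CPM and as log2 fold change ± standard error from the edgeR fit of 1 against 2 livers. AKR1B10, an aldo-keto reductase of the NRF2 response (ENSG00000198074, chromosome 7, 134527592 to 134541408, GRCh38), stood at 638 CPM against 0.0498 and 0.151 (12.60 ± 0.53), the healthy values resting on 2 and 6 counts. Its neighbour and close paralog AKR1B15 (chromosome 7, 134549136 to 134579875) had 901 counts against 1 count in both healthy livers together, a ratio of 1382 with an exact counting interval of 247 to 54662, and reads shared between the paralogs could add to it. EPS8L3 (chromosome 1, 109750080 to 109764027) had 768 counts in the APAP-ALF liver and 0 in both healthy livers, so it was at least 393-fold higher against a floor of 3 counts over the group. SPP1, which encodes osteopontin (chromosome 4, 87975650 to 87983426), stood at 1082 CPM against 5.45 ± 0.323 (SD, n = 2) and a log2 fold change of 7.63 ± 0.32. ALDH3A1, an aldehyde dehydrogenase (chromosome 17, 19737984 to 19748943), stood at 35.4 CPM against 0.0498 and 0.326 (7.54 ± 0.38).

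At the other end, SAA1 (chromosome 11, 18266174 to 18269977) differed by -7.05 ± 1.03, with its near-identical copy SAA2 at 36.3 CPM against 2415 and 2003 (-5.93 ± 0.60), and reads may be split between these copies. The vasopressin receptor gene AVPR1A (chromosome 12, 63142759 to 63150942) stood at 1.21 CPM against 280 and 137 (-7.43 ± 0.74). PLA2G2A, a secreted phospholipase (chromosome 1, 19975431 to 19980416), stood at 0.575 CPM against 452 and 23.8 (-8.68 ± 2.54). RET, a receptor tyrosine kinase gene (chromosome 10, 43077027 to 43130351), stood at 0.249 CPM against 6.48 and 46.1 (-6.70 ± 1.73), and for PLA2G2A and RET the healthy livers themselves stood far apart.

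**Figure D2:**
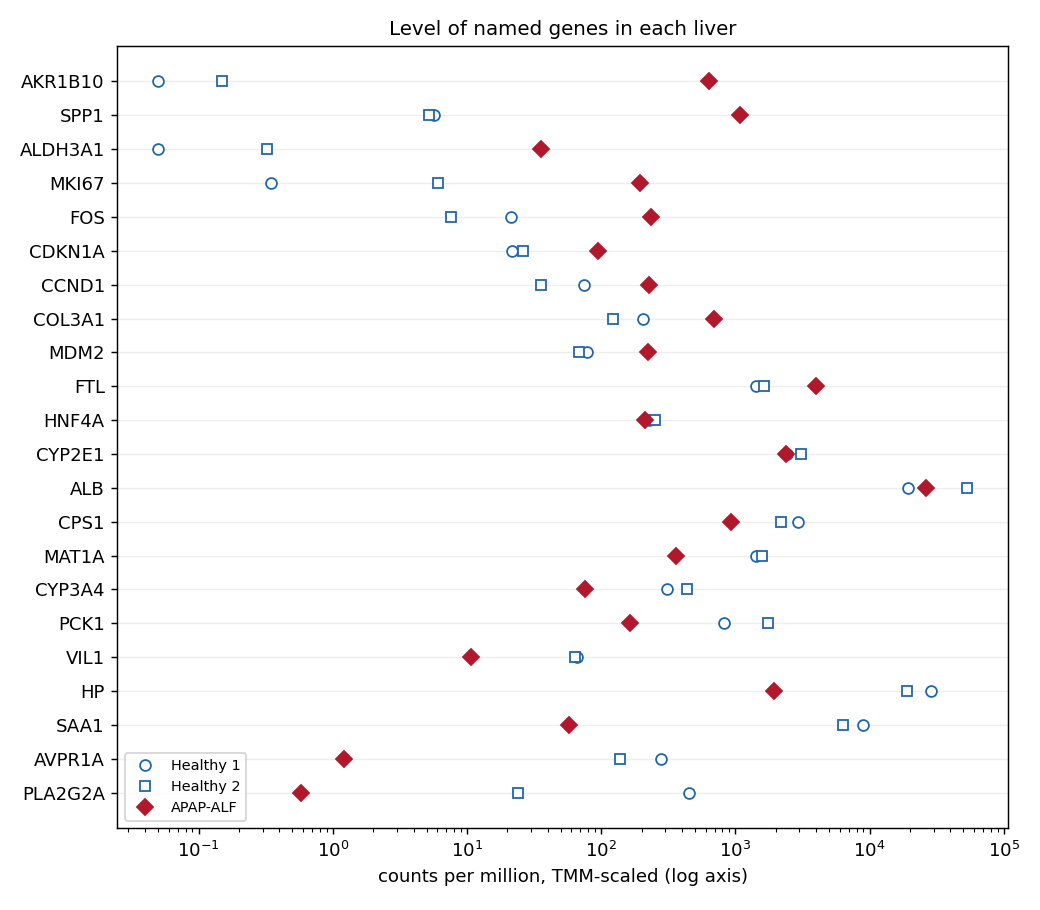
Level of 22 named genes in each liver in TMM-scaled CPM on a log axis, with the APAP-ALF liver as filled diamonds, Healthy 1 as open circles and Healthy 2 as open squares. AKR1B10 reaches 638 CPM in the APAP-ALF liver and SAA1 57.5 CPM, while HNF4A lies at 212 CPM beside 228 and 251.

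Gene groups were compared as 30 fixed lists. A member is counted as above or below only where the APAP-ALF liver lay at least 2-fold outside both healthy livers. No member of any list passed edgeR adjusted over all genes. Adjusted over the list alone, 152 memberships passed, 109 higher and 43 lower. That adjustment holds within a list and not across the 30 lists, and a gene in several lists is counted in each. For scale, the median of each list for Healthy 1 minus Healthy 2 is given beside the median for the APAP-ALF liver. Random lists of matched expression put 25 of the 30 list medians outside their central 95%, but 22 of 30 for the difference between the healthy livers, so that place does not mark a list as specific to the APAP-ALF liver. Where a single healthy liver as the reference moved a list's count by 3 or more members and over 1.5 times, or its median by over 1.5 times, that value is given with the list. Examples beyond those set by rule were picked after their values were seen.

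Cell division genes were higher. All 30 measured members of the cell cycle list lay above both healthy livers by at least 2-fold, all 30 passed edgeR adjusted over the list alone, and the median log2 fold change was 3.67, against -0.83 between the healthy livers. Besides MKI67 (5.93 ± 1.45), the mitotic genes CDC20, CCNB1 and CDK1 differed by 5.92 ± 0.63, 5.27 ± 0.42 and 5.55 ± 0.81, and CCND1, which encodes cyclin D1, stood at 226 CPM against 74.5 and 35.7 (2.03 ± 0.47). Of 20 p53 target genes, 8 lay above and 0 below, with a median of 1.16 against -0.42 between the healthy livers and 7 passing over the list alone. CDKN1A, the inhibitor of cyclin-dependent kinases, stood at 93.9 CPM against 21.7 and 26.0 (1.98 ± 0.24), and MDM2, which restrains p53, at 223 CPM against 78.3 and 68.9 (1.60 ± 0.24), while TP53INP1 had -0.47 ± 0.25. Immediate early genes had 11 of 21 members above and 0 below, with FOS at 234 CPM against 21.2 and 7.58 (4.02 ± 0.64) and DUSP1 at 1.45 ± 0.22, and 8 passed over the list alone. Their median of 1.39 was close to the 1.19 by which Healthy 1 exceeded Healthy 2, and MYC, at 28.6 CPM, lay between the 30.7 and 15.0 of the healthy livers. Against Healthy 2 alone, 18 immediate early genes lay above, with a median of 2.295.

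Acute phase genes were lower. Of 22 acute phase genes, 13 lay below and 0 above, 8 passed over the list alone, and the median was -1.26 against 0.29 between the healthy livers. HP, which encodes haptoglobin, stood at 1955 CPM against 28872 and 19035 (-3.62 ± 1.46), CRP at 1443 against 5548 and 3827 (-1.70 ± 0.68), and the fibrinogen gene FGA at 11627 against 27303 and 22116 (-1.09 ± 1.37). The coagulation and fibrinolysis list had 6 of 21 members below and 0 above (median -0.89, and -0.56 between the healthy livers), with 0 passing over the list alone. F11 and F9, which encode clotting factors, differed by -2.25 ± 0.49 and -2.19 ± 0.42, and FGB by -1.22 ± 1.20. Among 22 genes of the list of secreted plasma proteins, 5 lay below and 1 above, and 1 passed over the list alone. This list shares no gene with the acute phase list. It was not chosen to leave out all proteins of the acute phase response, and it holds SERPINA1 and HPX. The median of the 22 genes, -0.78, was about that between the healthy livers (-0.72) and became 0.05 against Healthy 1 alone. Against Healthy 2 alone, 12 of these genes and 13 coagulation genes lay below. ALB, which encodes albumin, stood at 26504 CPM, between 19221 and 53514, and APOB at -0.74 ± 1.21. Metallothionein genes had 6 of 9 members below, all 6 passing over the list alone, and a median of -2.27 against -0.27 between the healthy livers. MT1G stood at 27.7 CPM against 78.8 and 156 (-2.08 ± 0.52), and MT1M at 3.70 against 39.1 and 44.0 (-3.49 ± 0.30), whereas MT2A stood at 228 against 168 and 176 (0.41 ± 0.24). Metallothionein genes are similar in sequence, so their reads may be shared.

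In drug metabolism, the median of the P450 list was lower and that of the conjugation enzymes higher. In each list most members did not lie 2-fold outside both healthy livers (16 of 20 and 15 of 21), and no test compared the lists. Of 20 genes for cytochromes P450 and their reductase POR, 4 lay below both healthy livers and 0 above, with a median of -1.01 against 0.29 between the healthy livers and 0 passing over the list alone. CYP3A4 stood at 75.5 CPM against 309 and 438 (-2.31 ± 0.38) and CYP2C8 at 397 against 1057 and 1186 (-1.50 ± 0.38), and CYP2E1 had -0.20 ± 0.54, a sign that turned with library-size scaling. Conjugation enzymes had 5 of 21 members above and 1 below, 4 passing over the list alone, 3 of them higher, and a median of 0.48 against -0.56 between the healthy livers. UGT2B10 stood at 479 CPM against 45.4 and 142 (2.35 ± 0.69), UGT1A1, which conjugates bilirubin, at 201 against 58.5 and 83.2 (1.51 ± 0.30), and SULT2A1 at 219 against 755 and 996 (-2.00 ± 0.40). UGT1A isoforms share exons and UGT2B genes are similar, so reads may be shared. Bile acid genes went both ways, with 4 of 23 above, 2 below, 4 passing over the list alone and a median of -0.18 (-0.26 between the healthy livers) that became 0.06 with library-size scaling. FGF19, a hormone that represses bile acid synthesis, had 381 counts against 0, at least 195-fold higher against a floor of 3 counts over the group. Export genes SLC51B and ABCC4 differed by 4.48 ± 0.45 and 2.84 ± 0.31, the uptake transporter gene SLC10A1 by -2.32 ± 0.65, CYP7A1, the rate-limiting enzyme of bile acid synthesis, stood at 0.153 CPM against 1.10 and 3.89, and CYP8B1 differed by -1.09 ± 0.34 and ABCC2 by 0.65 ± 0.51. Among 20 liver-enriched transcription factor genes 2 lay below and 0 above, the median was -0.41 against 0.05 between the healthy livers, and 2 passed over the list alone. These were CREB3L3 (118 CPM against 351 and 325, -1.51 ± 0.28) and NR1I3 (8.48 against 35.5 and 39.4, -2.14 ± 0.27), and PROX1 had -1.13 ± 0.34. With a single healthy liver as the reference, 11 genes of the P450 list lay below Healthy 1 and 7 below Healthy 2 (median -0.62 against the latter). Above Healthy 1 lay 11 conjugation enzymes (median 1.24), and below Healthy 2 lay 5 bile acid genes (median -0.30).

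Of 26 urea cycle and amino acid genes, 11 lay below and 0 above, with a median of -1.11 against -0.29 between the healthy livers and 10 passing over the list alone, 9 of them lower. CPS1, the first enzyme of the urea cycle, stood at 929 CPM against 2908 and 2197 (-1.46 ± 0.53), and MAT1A, which makes the methyl donor S-adenosylmethionine, at 361 against 1433 and 1567 (-2.05 ± 0.42). Gluconeogenesis and fatty acid oxidation genes had 5 of 23 members below and 0 above, a median of -0.84 against -0.42 and 1 passing over the list alone. PCK1 stood at 164 CPM against 828 and 1762 (-2.98 ± 0.67) and ACSL1 at 412 against 1808 and 1505 (-2.01 ± 0.45). Zonation markers parted. Periportal genes had 9 of 17 members below and 1 above (median -1.46, and -0.67 between the healthy livers), with 6 passing over the list alone, 5 of them lower. Pericentral genes had 5 of 16 above and 1 below (median 0.75 against 0.32), with 7 passing over the list alone, 6 of them higher. The 5 above were the WNT targets AXIN2 (2.64 ± 0.47), LGR5 (3.47 ± 0.98), RHBG (2.54 ± 0.38), ZNRF3 (1.73 ± 0.30) and NKD1 (1.67 ± 0.29). GLUL, which makes glutamine from ammonia, fell just short of 2-fold above both, at 472 CPM against 236 and 189 (1.15 ± 0.29). ADH4 had 0.60 ± 0.31, and the 1 below was CYP3A4. Against Healthy 2 alone, 13 gluconeogenesis and fatty acid oxidation genes lay below and 8 pericentral genes above, the latter with a median of 1.14.

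Stress genes were uneven. NRF2 target and antioxidant genes had 7 of 24 members above and 0 below, a median of 0.96 against 0.34 and 5 passing over the list alone. FTL, the ferritin light chain, stood at 4001 CPM against 1427 and 1620 (1.39 ± 0.48), SQSTM1 at 437 against 126 and 92.3 (2.00 ± 0.30), HMOX1 at 73.8 against 31.6 and 43.6 (0.97 ± 0.29) and AKR1C1 at 316 against 274 and 130 (0.64 ± 0.50). The unfolded protein and integrated stress response list had 2 of 23 members above and 0 below, with a median of 0.04 (0.09 between the healthy livers) that became -0.06 under upper-quartile scaling. HSP90B1 and XBP1 had -0.50 ± 0.42 and -0.52 ± 0.31, and only GDF15, a stress-induced hormone (5.01 ± 0.29), passed over the list alone. Glycolysis and hypoxia genes had 3 of 23 above, among them HK2 (2.68 ± 0.47) and PKM (1.87 ± 0.37), 2 below, a median of 0.38 against -0.25 and 0 passing over the list alone. GAPDH differed by 0.88 ± 0.35 and LDHA by -0.25 ± 0.31. Of 11 fetal liver and carcinoma-associated genes, 3 lay above and 1 below, and AKR1B10 alone passed over the list alone. The median was 1.05 against -1.02 between the healthy livers, with AFP at 3.47 CPM against 0.523 and 2.28 (1.31 ± 0.88) and H19 at 71.6 against 115 and 339 (-1.66 ± 0.74). Above Healthy 2 alone lay 15 NRF2 targets, 5 unfolded protein and stress response genes and 6 glycolysis and hypoxia genes, and the fetal median was 0.59. Above Healthy 1 alone lay 6 glycolysis and hypoxia genes (median 0.65). The median of the unfolded protein and stress response list was -0.057 against Healthy 1 and 0.006 against Healthy 2.

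Among inflammatory cytokines and chemokines, 15 of 23 members lay above and 1 below, with a median of 2.45 against 0.25 between the healthy livers and 14 passing over the list alone, 13 of them higher. CCL2, which attracts monocytes, stood at 50.7 CPM against 7.22 and 2.31 (3.41 ± 0.67) and IL1B at 8.67 against 0.996 and 1.05 (3.08 ± 0.39), while CXCL2 stood at 42.7 against 156 and 144 (-1.81 ± 0.26). Markers of inflammatory cells did not move together. Monocyte and macrophage markers had 4 of 23 above and 0 below, 3 passing over the list alone, and a median of 0.57 against -0.81 between the healthy livers. TREM2 and GPNMB, found in macrophages that take up lipid and debris, stood at 7.90 CPM against 0.0996 and 0.351 (5.12 ± 0.54) and at 102 against 4.61 and 13.1 (3.52 ± 0.63). The general markers CD163 and CD14 had 0.64 ± 0.49 and 0.06 ± 0.57, the latter with its sign turned by upper-quartile scaling. Neutrophil markers had 2 of 12 members below and 0 above, a median of -0.69 against -0.29 and 0 passing over the list alone. CSF3R had -0.74 ± 0.44, and ALPL, at 54.6 CPM, lay between 66.1 and 49.5. Lymphocyte and plasma cell markers had 1 of 22 above and 1 below, 0 passing over the list alone, and a median of 0.07 (0.035 between the healthy livers) that became -0.03 under upper-quartile scaling. SDC1, which hepatocytes also express, had -0.20 ± 0.28, a sign that turned with library-size scaling. Against Healthy 1 alone, 13 monocyte and macrophage markers lay above and 3 below (median 1.245), the neutrophil median was -0.33 and the lymphocyte median 0.23. Against Healthy 2 alone, 8 monocyte and macrophage markers and 5 lymphocyte markers lay above and 5 neutrophil markers below.

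Stellate cell, fibroblast and matrix genes had 14 of 24 members above and 0 below, 12 passing over the list alone, and a median of 1.31 against 0.32. The collagen genes COL3A1 and COL1A1 stood at 688 CPM against 205 and 123 (2.07 ± 0.39) and at 381 against 127 and 55.8 (2.06 ± 0.52), FN1 had 0.92 ± 0.56, and ACTA2, a marker of activated stellate cells, lay between the healthy livers at 26.9 CPM against 31.4 and 15.8. Cholangiocyte and progenitor markers had 14 of 19 above and 0 below, 13 passing over the list alone, and a median of 2.06 against -0.17. KRT19, a bile duct keratin, stood at 12.2 CPM against 0.299 and 0.778 (4.50 ± 0.60), KRT7 had 2.06 ± 0.53 and SOX9 1.75 ± 0.48, and ANXA4 had 0.41 ± 0.23. Endothelial markers had 5 of 18 members below and 1 above, 8 passing over the list alone, 7 of them lower, and a median of -0.66 against 0.21. STAB2, a scavenger receptor of sinusoidal endothelium, stood at 27.6 CPM against 82.9 and 65.3 (-1.43 ± 0.29), and STAB1 had -0.36 ± 0.27. Of 6 erythroid and platelet genes (median 1.25, and -1.18 between the healthy livers) 3 lay above, all globin genes, with HBB at 21.8 CPM against 3.09 and 8.21 (1.95 ± 0.60) and HBA2, which shares reads with its copy HBA1, at 2.47 ± 0.64. Mitochondrially encoded mRNAs had 1 of 13 below and 0 above and a median of -0.34 against 0.19, with MT-CO1 and MT-CO3 at 0.06 ± 0.77 and 0.19 ± 0.58, the former with its sign turned by upper-quartile scaling. Cytosolic ribosomal protein genes had 0 of 25 outside, a median of 0.22 against -0.41, RPLP0 at -0.07 ± 0.35, whose sign turned with library-size scaling, and RPL4 at 0.32 ± 0.34. In these 3 lists 0 members passed over the list alone. Of pancreatic and gut epithelial genes 3 were measured, and VIL1, at 10.7 CPM against 66.1 and 63.8 (-2.60 ± 0.26), passed over the list alone. LGALS4, at 38.7 CPM, lay between 6.43 and 151, and the list median of -1.03 (-1.15 between the healthy livers) became 0.22 against Healthy 1 alone and -1.97 against Healthy 2 alone. Of the endothelial markers, 9 lay below Healthy 1 alone, and their median was -0.31 against Healthy 2 alone. The erythroid median was 0.80 and the mitochondrial one -0.165 against Healthy 2, and the ribosomal one was 0.40 against Healthy 1 and 0.02 against Healthy 2.

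Some list medians depended on the scaling. Library-size scaling moved 11 of them by over 1.5 times. Besides the bile acid list, these were conjugation enzymes (0.745), liver-enriched transcription factors (-0.172), plasma proteins (-0.52), the unfolded protein and stress response (0.283), and glycolysis and hypoxia genes (0.643). The others were the neutrophil (-0.447), lymphocyte (0.313), endothelial (-0.421), mitochondrial (-0.099) and ribosomal (0.474) medians. Upper-quartile factors moved the bile acid median to -0.282 and the ribosomal one to 0.125, and limma-voom the pancreatic and gut one to -0.391. The authors' deposited table holds only part of these lists, and there the median of 6 cell cycle genes was 2.045, of 14 p53 targets 0.647 and of 18 bile acid genes -0.339. Of the lists' members in the authors' deposited table, the 3 neutrophil markers had a median of -0.457, 3 lymphocyte markers -0.296 and 17 unfolded protein and stress response genes -0.12.

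**Figure D3:**
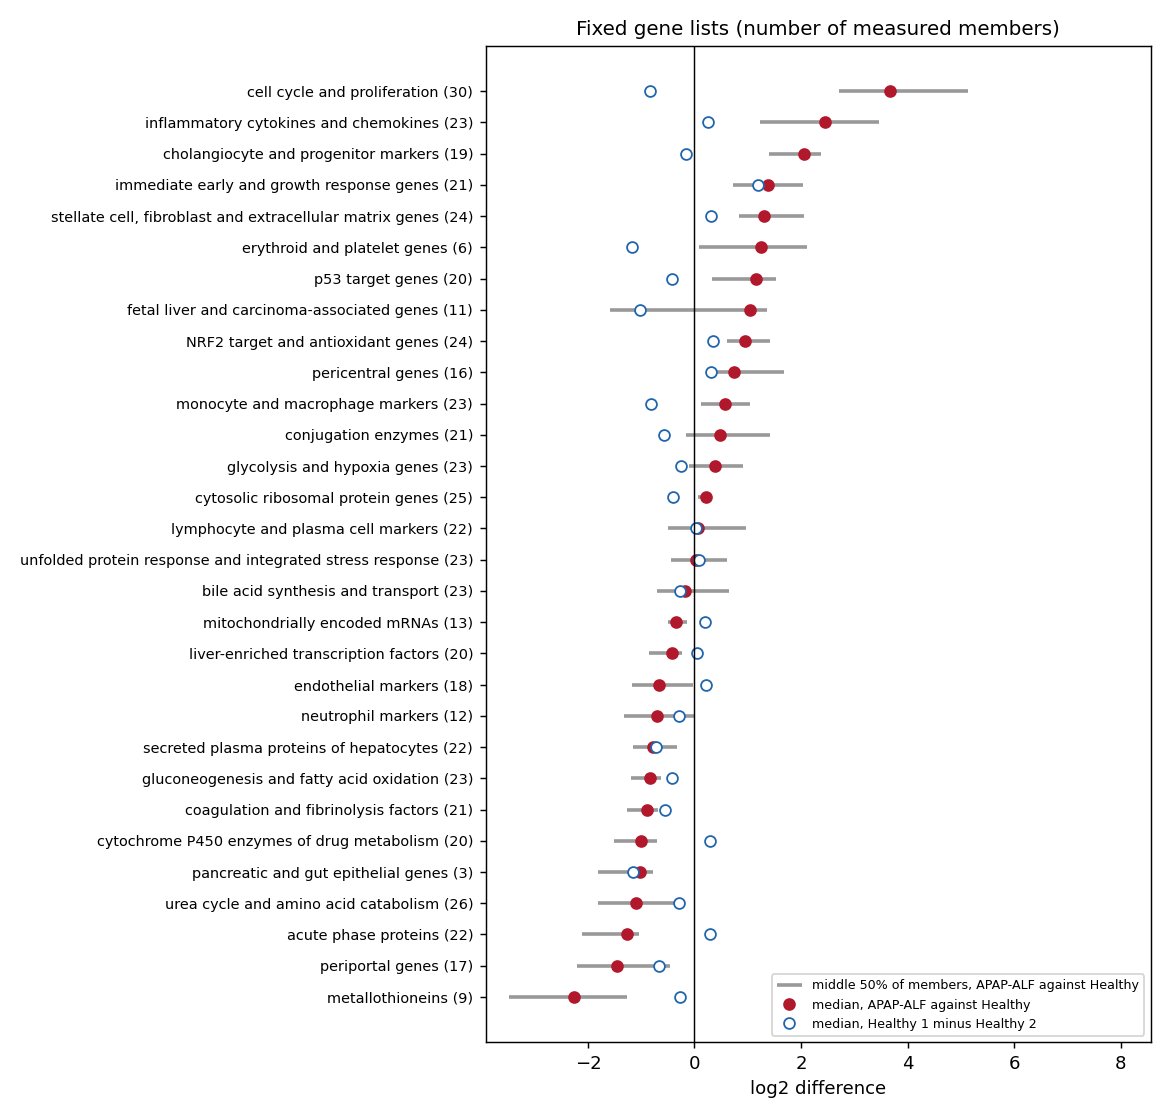
Median log2 difference of each of the 30 fixed gene lists, with the number of measured members in brackets, for the APAP-ALF liver against the healthy livers (red, grey bar the middle 50% of members) and for Healthy 1 minus Healthy 2 (open blue). The cell cycle median is 3.67 against -0.83 between the healthy livers, and the acute phase median is -1.26 against 0.29.

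The authors' deposited normalized table holds the same counts divided by 1 constant per library, so its differences follow those of the raw counts by construction and are no independent check. Of 8713 genes in both, 95.9% had the same sign as the edgeR fit, and the Pearson correlation across genes, which are not independent replicates, was 0.994.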

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

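One alternative, the fit of only the genes in the authors' normalized table, was chosen after the data were seen; all others were set before. The 0 calls of the edgeR test were also seen under DESeq2's size factors in edgeR, no filter, limma-voom, the legacy quasi-likelihood method, and without mitochondrial genes and the 20 highest genes. A 2-fold minimum gave 0 as well, which follows from the main result because it is the stricter test. As edgeR recovered 0% of changes in the simulations with gene scatter, a repeated 0 does not show stability. Calls appeared with library-size scaling (238 higher, 28 lower), where all genes shift by 0.24 on the log2 scale, with upper-quartile factors (3 higher, SPP1, AKR1B10 and AKR1B15), among genes at 1 CPM or more in every library (48 and 13, fewer genes tested), with DESeq2 (628 and 478) and among the 8715 genes in the authors' table (1 higher, ACSL4, and 1 lower). With library-size scaling 76.9% of genes at an unadjusted p under 0.05 were higher, against 59.1% in the main fit and 50.9% with upper-quartile factors. Adjustment over each list alone gave 152 calls against 0 over all genes.

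The 4-fold counts of 729 and 301 became 116 and 78 among genes at 1 CPM or more in every library, 2296 and 1658 at 2-fold, and 1341 to 1360 and 618 to 847 without one of the healthy livers. A prior count of 0.5 gave 457 lower. With RLE, library-size or upper-quartile factors, or no filter, they stayed within 1.5 times. Library-size scaling turned the signs of CYP2E1 to 0.053, UGT2B4 to 0.093, ALPL to 0.154, SDC1 to 0.042, RPLP0 to 0.187 and HNF4A to 0.072. Upper-quartile factors turned CD14 to -0.038 and MT-CO1 to -0.041, and limma-voom turned LGALS4 to 0.310. Except where stated, the cause was not tested. Of 400 alternative values of named genes with a test, 349 kept sign and side of the threshold, 42 passed it and 9 changed sign. Of 192 without a test, 7 changed sign, all against a single healthy liver (ALB, MYC, CD14, ALPL, MT-CO1, RPLP0 and LGALS4). Of 263 alternative list medians, 8 changed sign and 52 moved by more than the spread between the healthy livers. Leaving out a healthy liver left 1 library per group, so it gives values and no test. No paired analysis was possible because the labels number the healthy livers only. Genes below about 1 CPM rest on few counts, and their folds depend on the prior count.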

Other observations

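The 12 gene lists described first and all tests of explanations in this part were chosen after the results were seen, while the other lists these tests use are fixed ones. Cholesterol synthesis and uptake genes were lower as a group in the APAP-ALF liver. Of 23 members, 18 lay at least 2-fold below both healthy livers and 0 above, with a median log2 fold change of -1.71 against -0.45 for Healthy 1 minus Healthy 2. INSIG1 stood at 72.5 CPM against 600.1 and 543 (-2.98 ± 0.34) and SQLE at 16.5 against 56.1 and 95.7 (-2.20 ± 0.44). Fatty acid synthesis genes had 3 of 13 below and a median of -0.57 against -0.19, with SCD at -0.15 ± 0.31. Glucocorticoid-responsive genes had 6 of 12 below and 1 above (median -1.22 against -0.03, and -0.74 against Healthy 1 alone), among them ZBTB16 (-2.52 ± 0.36) and FKBP5 (-1.79 ± 0.30), and 4 of the 12 are also in a fixed list.

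Lipid-associated macrophage genes had 9 of 16 members above and 0 below, with a median of 1.96 against -0.02, among them FABP4 (5.65 ± 0.64) and LPL (4.55 ± 0.76). Of these 16 genes 4 are also in a fixed list. Spindle and kinetochore genes had 15 of 16 above, with a median of 5.35 against -1.39. WNT target genes had 8 of 12 above (median 1.70 against 0.29), with NOTUM at 12.7 CPM against 1.30 and 0.929, and 8 of the 12 are also in a fixed list. Interferon-stimulated genes had 3 of 18 above (median 0.52 against -0.46) and YAP and TEAD target genes 6 of 14 (median 0.64 against 0.40). IL-6 and STAT3 response genes, of which 9 are also acute phase genes, had 7 of 16 below (median -1.13 against 0.39), and the receptor gene IL6R stood at 36.2 CPM against 91.7 and 107. Sinusoidal endothelial genes had 5 of 9 below (median -1.23 against 0.25), whereas vascular endothelial genes had a median of -0.01 against 0.11, and all 9 of each are fixed endothelial markers. Hepatocyte plasma proteins outside the acute phase list had 5 of 27 below (median -0.79 against -0.87), and all 27 are in fixed lists. Their median was -0.07 against Healthy 1 alone, and 16 lay below Healthy 2 alone. The interferon median was 0.90 against Healthy 1 alone, with 8 genes above, and 0.31 against Healthy 2 alone. Below Healthy 1 alone lay 8 sinusoidal endothelial genes, and the vascular median was 0.06 against Healthy 1 and 0.005 against Healthy 2.

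The authors' normalized table held few of the genes that were high in the APAP-ALF liver alone. Among genes with a symbol it listed 19 of the 656 that lay at least 4-fold above both healthy livers (2.90%) and 70 of the 200 that lay at least 4-fold below (35.0%). The second-highest of the 3 values was never below 8.82 units in any gene listed, so a gene near 0 in both healthy livers is not in it.

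Acute phase genes were lower in the APAP-ALF liver. A lower share of hepatocyte RNA would lower the conjugation enzymes, also made by hepatocytes, by about as much. Their median lay at least 1.745 (log2) above the acute phase median against either healthy liver. The widest gap among 9 hepatocyte lists between the healthy livers was 1.009. The conjugation list was the highest of the 9 and its own difference (median 0.48) may widen the gap, so it cannot decide the question. Other medians were lower too (urea cycle and amino acid catabolism -1.11, P450 -1.01, coagulation -0.89, gluconeogenesis and fatty acid oxidation -0.84). The lowest other hepatocyte median minus the acute phase one was 0.427 against Healthy 1 and -0.009 against Healthy 2, within that 1.009. Against Healthy 2 it was the median of the urea cycle and amino acid list (-1.272, beside -1.263 for the acute phase list). A lower share thus stays open. A high acute phase level in the healthy livers stays open, since SAA1 ranked at place 9 among their nuclear protein-coding genes and no other reference liver was analysed here. A lower acute phase response in this patient's hepatocytes may also account for it and was not tested.

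Cholangiocyte and matrix genes were higher. A lower hepatocyte share would raise markers of all other cell types alike, but the lower of these medians exceeded the lowest of the endothelial, neutrophil, lymphocyte, macrophage and erythroid medians by at least 1.946, where the widest gap among these 7 lists between the healthy livers was 1.498. Against Healthy 1 the macrophage (1.245) and erythroid (1.847) medians lay above the matrix median (1.193), so a lower share is argued against as the only cause and stays open as a part of it. More cholangiocytes could account for the bile duct part and cannot be told apart from more transcript per cell, since 5 of 19 markers stayed under 2-fold above both healthy livers and some of these are also expressed by hepatocytes.

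Pericentral genes were higher relative to periportal genes. Their median exceeded the periportal one by 2.005 against Healthy 1, by 2.709 against Healthy 2, and by 0.993 between the healthy livers. WNT target genes alone may carry the gap. Without them it was 1.207 against Healthy 1 and 2.151 against Healthy 2, on either side of the 1.266 between the healthy livers. The 8 other pericentral genes had medians of -0.016 against Healthy 1 and 0.578 against Healthy 2, and 0.592 between the healthy livers. The WNT target list was written after the results were seen and holds all pericentral genes counted as above. A lower median of the 8 genes left was thus built in, and it cannot decide whether the whole pericentral list rose. The periportal medians were -1.224 and -1.573, and -0.674 between the healthy livers. Whether the lower periportal genes reflect a shift of zones cannot be told from these values. One patient's explant cannot show what holds for the condition.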
